A study of Mus musculus with 6 samples.

How the data were processed

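RNA from otocysts of Chd7 wild type, heterozygous and homozygous embryos was sequenced as polyadenylated RNA in 2 libraries per genotype, per the labels. Groups were taken from the genotype label of each sample. The deposited tables are 4 lists of called genes, 1 for each direction of the heterozygous and of the homozygous comparison with wild type. Each gives a gene symbol, a log2 fold change and an adjusted p, both computed by the authors before deposit. The log2 fold changes in the authors' deposited table are mutant relative to wild type, as the sign of the lists and the fall of Chd7 in both genotypes show. The deposited adjusted p-values all lie under 0.05. Of them, 10 in the heterozygous and 41 in the homozygous lists are given as 0 in the authors' deposited table, so genes tied at 0 were ordered by symbol. The submitters' processing notes name Bowtie2 2.0.6, DESeq 1.22.1 and the mouse build mm9, with no roles. The steps between reads and lists, any filter on low counts and the counting of reads shared between paralogues are not given in the sources used here.

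Because the values are comparisons rather than libraries, the depth per library is unknown, and no standard error, normalised count or replicate value stands behind a fold. Genes absent from a list may have failed the threshold or may not have been measured, so absence is written as not listed. The count-based test planned for the case of per-library counts was not run, and the authors' calls were taken as deposited. No fold in the lists is infinite.

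From these lists 28 gene lists, holding 864 distinct genes, were compared with the calls. The lists have 916 entries, so some genes are counted in more than 1 list. The lists were fixed before the data were examined and covered otic patterning, neuroblasts, neural crest, mesenchyme, hindbrain, surface ectoderm, blood, endothelium, macrophages, muscle, signalling pathways, retinoic acid, low oxygen and glycolysis, stress, ribosomal protein, sex-linked, imprinted, deafness, Hox, cell cycle, matrix and chromatin remodeller genes. For lists with at least 3 called members, a two-sided Fisher's exact test compared membership with direction among all called homozygous genes, with Benjamini-Hochberg adjustment over the 19 lists tested. Called genes alone form the background, so the test asks whether a list leans one way more than other called genes do and not whether it holds more calls than chance. Members of a pathway are co-regulated, and the test treats genes as independent, so its p-values are too small to an unknown degree. On simulated directions for 1085 genes, random lists had an unadjusted p under 0.05 by this test in 1.5 to 6.5% of draws. Lists set 95% higher did so in 73% of draws with 5 members and 98.5% with 10. Lists set toward lower were not simulated. As most calls were lower, such lists are harder to detect, and adjustment over lists makes passing harder in both directions. An adjusted p also depends on the p-values of the other lists. These are taken as they were where a list is said to be unable or too small to pass.

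Deposited symbols were matched to the GENCODE M21 annotation, directly or through synonyms: 1078 of 1085 homozygous and 137 of 138 heterozygous genes matched. As that annotation is of another build than the one the submitters name, no coordinates are given, and it served for names, transcript lengths and for which genes neighbour Chd7. Transcript lengths were compared between higher and lower genes by a two-sided permutation test of the difference in median log2 length with 100000 resamples. Overlap between the 2 comparisons was compared with independent lists and with 1000 simulated draws of unchanged groups sharing 2 control libraries, with Gaussian errors and equal libraries. In each draw the numbers of genes called were set to those listed, taken from the ends of the ranking without a test. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

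Genes named in the text follow a rule fixed before the data were examined: Chd7, Aldh1a3, the 8 largest folds and the 4 smallest adjusted p-values in each direction, up to 4 called members of each list by adjusted p, and any gene called in both comparisons. The planned minimum on mean normalised count could not be applied, and predicted genes were passed over. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives were stricter adjusted p, a minimum fold, matched symbols alone, other gene totals, other windows around Chd7 and, added after seeing the data, the shorter and the longer called genes taken alone, divided at their median transcript length, and other measures of length. No group has 4 or more libraries, and values per library were not used here, so no search for outlying libraries was made.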

Results

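Gene expression was measured by RNA sequencing in otocysts, the epithelial vesicles that form the inner ear, dissected from mouse embryos at embryonic day 10.5. The embryos carried 0, 1 or 2 copies of the Gt allele of Chd7, in mouse nomenclature a gene trap, in the B6129SF1/J strain. Chd7 encodes a chromatin remodelling enzyme of the chromodomain helicase family whose loss in people underlies CHARGE syndrome. Each of the 3 genotypes, wild type, heterozygous and homozygous, was represented by 2 libraries. The deposited values were lists of genes called different between a mutant genotype and wild type, each with a log2 fold change and an adjusted p. Values per library were not used here, so the depth is unknown and no spread between replicates stands beside the folds. The labels do not say that the 2 libraries of a genotype came from separate embryos, so the adjusted p-values measure only the spread between these samples, which may be technical.

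The homozygous comparison asked what changes in the otocyst when both Chd7 alleles carry the trap. Chd7 itself fell to 22.4% of wild type (log2 -2.16, adjusted p 1.54e-10 in the authors' deposited table). Aldh1a3, which encodes an enzyme that makes retinoic acid and is named in the series title, rose 5.97-fold (log2 2.58, adjusted p 2.84e-07 in the authors' deposited table). The largest log2 folds among the higher genes in the authors' deposited table were those of the X-inactivation transcript Xist (9.64), the vasodilator peptide gene Adm (5.90) and the heat shock genes Hspa1a (5.47) and Hspa1b (4.99). The labels do not give the sex of the embryos, which may differ between the genotypes and by itself changes Xist. Whether such a difference also moved other calls was not tested. Among the lower genes the largest were those of the taste transducin gene Gnat3 (4.42% of wild type), the otic homeobox gene Otx1 (5.42%), the otoconial matrix gene Otol1 (5.64%) and the proneural gene Neurod4 (5.72%) in the authors' deposited table. In all, 416 genes were listed as higher and 669 as lower, 61.7% of the calls. Their median log2 folds were 1.31 and -1.35 in the authors' deposited table. Of the 28 gene lists, 19 had enough called members to be tested for direction among the called genes, and 4 passed after adjustment, 3 toward higher and 1 toward lower.

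The genes of glycolysis and the response to low oxygen rose together in homozygotes. Of the 33 genes in that list, 31 were called, all higher, with a median log2 fold of 2.27 in the authors' deposited table (two-sided Fisher's exact test, adjusted p 1.16e-12). They included the glucose transporter gene Slc2a3 (18.3-fold), the glycolytic enzyme gene Eno2 (13.8-fold), the mitophagy gene Bnip3 (10.3-fold) and the mTOR inhibitor gene Ddit4 (7.68-fold), as given in the authors' deposited table. None of the 33 was listed in heterozygotes, which was not tested as a difference between the genotypes. The list of heat shock and immediate early genes had 8 called members of 31, all 8 higher, with a median log2 fold of 2.75 in the authors' deposited table (Fisher's exact test, adjusted p 0.00213). Beside the near-identical Hspa1a and Hspa1b, between which reads can be split, it held the stress-induced genes Ier3 (log2 3.50) and Fos (3.37) in the authors' deposited table. Of 65 ribosomal protein genes, 46 were not listed and 19 were called, all 19 higher, with a median log2 fold of 0.89 in the authors' deposited table (Fisher's exact test, adjusted p 9.02e-08). Examples are Rpl22l1 (log2 1.39), Rps27a (0.82), Rpl38 (0.73) and Rpl19 (0.69), as listed in the authors' deposited table, with the caution that ribosomal protein genes share reads with many processed pseudogenes.

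Transcript length moved with direction across the homozygous calls. The longest annotated transcript had a median of 2698 nt among higher genes and 4868 nt among lower genes, a difference of 0.85 on the log2 scale (two-sided permutation test, p 1e-05, the smallest these permutations can give). All 19 ribosomal protein genes, 7 of the 8 heat shock and immediate early genes and 25 of the 31 low-oxygen and glycolysis genes were among the shorter called genes, those up to the median of 4092 nt. Among these shorter genes alone all of these members were higher, with adjusted p-values by Fisher's exact test of 0.00023 for the ribosomal list, 1.43e-05 for the low-oxygen and glycolysis list and 0.0748 for the heat shock list, for which 7 of 7 is the most extreme outcome and could not pass. The ribosomal members had a median length of 1059 nt, well under that of all higher genes. The division at the median therefore does not remove length for this list, and a length difference stays open for it. At an absolute log2 fold of at least 1 the ribosomal list had 4 members left, all 4 higher, too few to pass (Fisher's exact test, adjusted p 0.0719).

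**Figure D1:**
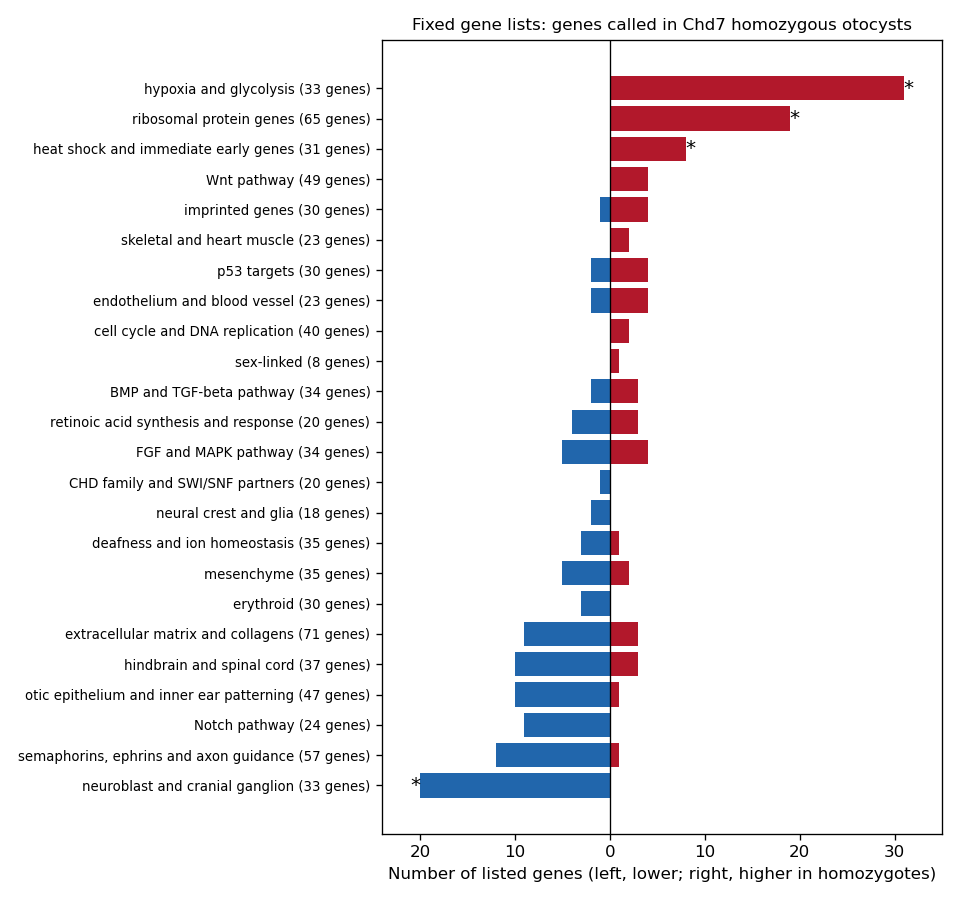
Number of called members of each fixed gene list in homozygous against wild type otocysts, with genes listed as lower in blue to the left of 0 and as higher in red to the right; the size of each list is in brackets. Asterisks mark the 4 lists past an adjusted p of 0.05 by Fisher's exact test: 31, 19 and 8 members to the right and 20 to the left.

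Genes of differentiating neuroblasts and cranial ganglia fell in homozygotes. Of 33 in the list, 20 were called and all 20 were lower, with a median log2 fold of -2.07 in the authors' deposited table (Fisher's exact test, adjusted p 0.000491). They included Neurod4, the growth-cone gene Stmn2 (log2 -2.49), the neuronal RNA-binding protein genes Elavl4 (-2.29) and Elavl2 (-1.48), and the neurofilament gene Nefm (-1.99), all from the authors' deposited table. Of these 20 genes, 14 were among the shorter called genes and 6 among the longer. Among the longer genes 81.0% of the other calls were also lower, so that 6 of 6 lower could not pass the test there (Fisher's exact test, adjusted p 0.685). The hindbrain and spinal cord list, markers of the neural tube beside the otocyst, had 10 lower and 3 higher of 37 (adjusted p 0.495 by Fisher's exact test). Its lower members included the homeobox genes Gsx1 (log2 -3.39), Lhx2 (-3.16) and Barhl1 (-1.99), and its higher members included the signalling gene Wnt1 (3.19) and Nkx6-2 (1.13), in the authors' deposited table.

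Of 47 otic epithelium and patterning genes, 10 were listed as lower, 1 as higher and 36 were not listed, and the list did not pass the test (Fisher's exact test, adjusted p 0.141). Besides Otx1 and Otol1, the placodal regulator Eya1 (log2 -1.33) and the T-box gene Tbx3 (-1.16) fell, and the growth factor gene Bmp4 (1.78) rose, in the authors' deposited table. Notch pathway genes, which restrict neuroblast formation in the otic epithelium, had 9 called members of 24, all 9 lower (Fisher's exact test, adjusted p 0.0581). Its unadjusted p by the same test was 0.0153. With 9 called members this is the most extreme outcome toward lower. Given the p-values of the other lists, it could not pass after adjustment in that direction. Their log2 folds in the authors' deposited table included Dtx4 at -1.67, the ligand gene Dll3 at -1.65, the feedback inhibitor gene Nrarp at -1.56 and Hes6 at -1.37. Of 57 axon guidance genes, 12 were lower and 1 higher (Fisher's exact test, adjusted p 0.0588), among them the ephrin receptor genes Epha5 (log2 -3.32) and Epha3 (-3.24), Robo3 (-3.74) and Sema3d (-2.45) in the authors' deposited table. All 12 lower members were among the longer called genes, where most other calls were lower too and 12 of 12 could not pass (Fisher's exact test, adjusted p 0.466). A length difference therefore stays open for this list.

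Retinoic acid genes changed in both directions in homozygotes, with 3 higher and 4 lower of 20 (Fisher's exact test, adjusted p 1). Of the retinaldehyde dehydrogenase genes, Aldh1a3 rose while Aldh1a2 (log2 -2.70) and Aldh1a1 (-2.59) fell in the authors' deposited table. Aldh1a1 and Dhrs3 were chosen after their values were seen. The retinoic acid receptor gene Rarb (1.92) and the retinaldehyde reductase gene Dhrs3 (1.10) rose, and the retinoic acid degrading enzyme gene Cyp26b1 (-1.21) and the nuclear receptor gene Nr2f1 (-0.99) fell, all on the log2 scale of the authors' deposited table. Of 49 Wnt pathway genes, 4 were called, all 4 higher (Fisher's exact test, adjusted p 0.0588): Wnt1, Wnt11 (log2 2.10), the Wnt target Sp5 (1.49) and Dkk3 (1.43) in the authors' deposited table. The unadjusted p by the same test was 0.0214. With 4 called members this is the most extreme outcome toward higher. Given the p-values of the other lists, the list was too small to pass after adjustment. All 4 were among the shorter called genes, where more of the other calls were higher (Fisher's exact test, adjusted p 0.285).

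The FGF and MAPK list had 4 higher and 5 lower of 34 (Fisher's exact test, adjusted p 0.826), with Fgf15 at 3.83 and Fgf20, a ligand needed for cochlear sensory development, at -4.02 on the log2 scale of the authors' deposited table. Mesenchyme markers, from the tissue around the vesicle, had 2 higher and 5 lower of 35 (Fisher's exact test, adjusted p 0.826). Among them Pou3f4, a deafness gene of the periotic mesenchyme, was at -4.00, Postn at -2.62 and Dlk1 at 1.61 on the log2 scale of the authors' deposited table. How much of the surrounding tissue each dissection held was not measured, so these changes cannot be assigned to the genotype.

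**Figure D2:**
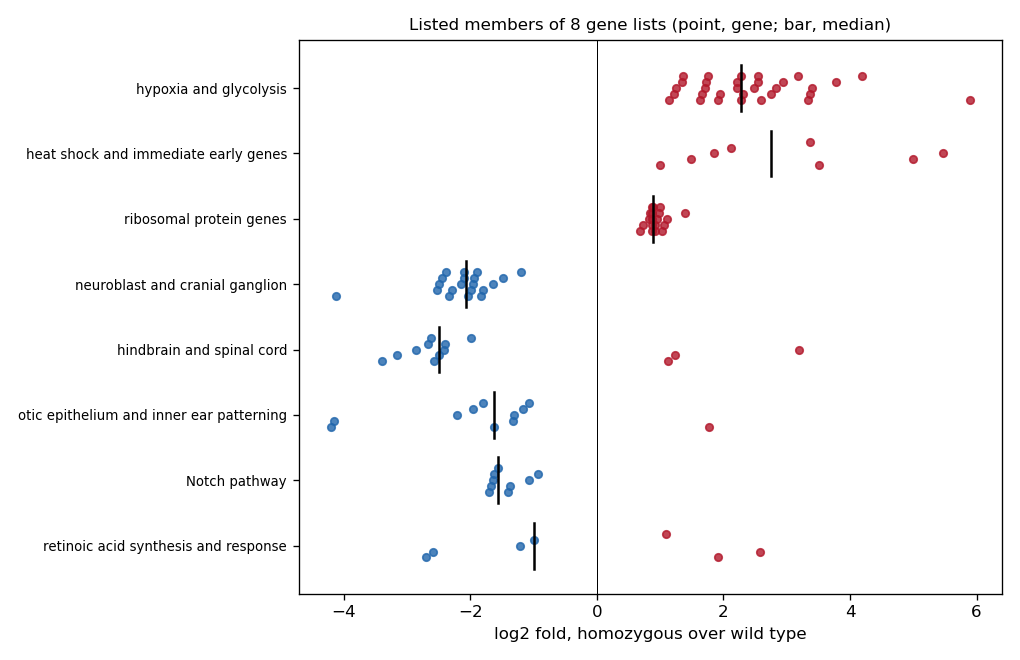
Log2 fold of homozygous over wild type otocysts for each called member of 8 gene lists, from the authors' deposited table; each point is a gene, red where higher and blue where lower, and each bar is the list's median. The low-oxygen and glycolysis members lie above 1 with a median of 2.27, and the neuroblast and ganglion members below -1 with a median of -2.07.

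The heterozygous comparison asked what changes when 1 allele carries the trap. Chd7 fell to 67.1% of wild type (log2 -0.57, adjusted p 7.27e-07 in the authors' deposited table), and Aldh1a3 rose 3.02-fold (log2 1.59, adjusted p 1.92e-07 in the authors' deposited table). The calls numbered 43 higher and 95 lower genes, with median log2 folds of 0.94 and -0.72 in the authors' deposited table. The largest fall was that of the signal gene Shh, made by the floor plate of the neural tube, to 2.16% of wild type (log2 -5.54) in the authors' deposited table. Large falls were also those of the transcription factor genes Foxa2 (-3.42), Lhx4 (-3.38), Foxa1 (-3.32) and Nkx2-2 (-3.02), on the log2 scale of the authors' deposited table. Of the 37 genes in the hindbrain and spinal cord list, 10 were called and all 10 were lower. In homozygotes 3 of these 10 were also lower, 1 was higher and 6 were not listed, Shh and Foxa2 among them. How much neural tube each dissection held was not measured, so these falls cannot be assigned to the genotype. The largest rises in the authors' deposited table were those of Pisd-ps1 (log2 4.99), a pseudogene whose reads can belong to its parent gene, the neutrophil calprotectin gene S100a9 (4.59) and the Hox gene Hoxc4 (3.11). As the tissue in each dissection was not measured, these rises cannot be assigned to the genotype either.

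Extracellular matrix genes had 8 called members in heterozygotes, all 8 lower, and erythroid genes 4, all 4 lower, including Hbb-b2 (log2 -2.44 in the authors' deposited table), a globin gene that shares reads with its near-identical paralogue. Of all heterozygous calls 68.8% were lower. Mesenchyme markers had 1 higher and 4 lower. Of the neural crest and glia list, 3 members were higher and 1 lower, including the melanoblast enzyme gene Dct (log2 1.39), Pax3 (0.93) and Tfap2b (0.64) in the authors' deposited table. Its lower member was Postn, which the matrix and mesenchyme counts also hold. The neuroblast and ganglion list had 3 called members of 33, with Dcx (log2 0.21) and Pou4f1 (0.54) higher and Neurod4 (-0.93) lower in the authors' deposited table. The otic epithelium list had 1 called member of 47, the guidance cue gene Ntn1, which was lower (log2 -1.37 in the authors' deposited table). The Notch pathway, the low-oxygen and the heat shock lists had 0 called members. The heterozygous lists were counted and not tested, and at most 10 members of a list were called.

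Whether the same genes changed with 1 and with 2 trapped alleles was asked of the 56 genes called in both comparisons, 40.6% of the heterozygous calls. Of these, 48 moved in the same direction, 43 lower and 5 higher (two-sided Fisher's exact test of direction against direction, p 0.00285). That p takes the comparisons as independent, and since the shared wild type libraries by themselves push genes called in both toward the same direction, it does not show a shared effect. The 5 higher genes were Aldh1a3, the FGF ligand gene Fgf15 (log2 1.37 and 3.83, heterozygous first), the endothelial scavenger receptor gene Stab2 (1.44 and 2.23), Dlk1 (0.40 and 1.61) and 2610507I01Rik (1.85 and 1.85), by the authors' deposited table. The lower genes included Chd7, Neurod4 (-0.93 and -4.13), Pou3f4 (-0.83 and -4.00), Slitrk6 (-0.62 and -3.78), a gene needed for inner ear innervation, Lhx8 (-1.96 and -4.03) and Postn (-0.72 and -2.62), also log2 values of the authors' deposited table. Pou3f4 and Postn are in the mesenchyme list, and the surrounding tissue in each dissection was not measured. The other 8 genes went opposite ways. The axon guidance receptor gene Robo3 (1.59 and -3.74), the sensory neuron gene Pou4f1 (0.54 and -1.96), Kirrel2, Xkr7 and AI506816 were higher in heterozygotes and lower in homozygotes in the authors' deposited table. Nkx6-2 (-1.87 and 1.13), Kbtbd11 and Sparcl1 were lower in heterozygotes and higher in homozygotes in the authors' deposited table.

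Both comparisons used the same 2 wild type libraries, which makes their calls overlap with no effect at all. In the simulation, unchanged groups were ranked against shared controls, and as many genes were taken from each end as were listed. It therefore does not show how many calls unchanged groups would give. With the numbers called set in this way, 43 genes were called in the same direction on average. Of the draws, 95% lay between 32 and 54, and 0.004 genes on average went in opposite directions. Of the 43, 12.5 were higher in both (7 to 19) against 5 observed, and 30.6 were lower in both (22 to 39) against 43 observed. Independent lists of these sizes among 21924 protein-coding genes would share 0.816 higher and 2.90 lower genes, and 3.11 in opposite directions. The simulated values depend on the number of genes assumed: for 15000 and 10000 genes the same-direction means were 49.2 and 56.9, and the ranges for genes lower in both were 26 to 44 and 32 to 50. The observed sum of 48 lies within the range with no effect under each total, and the 43 lower genes lie above theirs under the largest total alone. The 5 higher genes lie below their range, and the 8 genes with opposite directions above theirs, under all the totals. The 43 lower genes include the trapped gene Chd7 itself (log2 -0.57 in heterozygotes and -2.16 in homozygotes in the authors' deposited table). Part of the same-direction overlap may come from the shared controls. With 2 wild type libraries the controls could not be split into 2 sets of 2, so the size of that part was not tested.

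The change was larger in homozygotes for 46 of the 48 genes called in the same direction, the exceptions being the neuropeptide receptor gene Adcyap1r1 (log2 -1.11 and -0.79, heterozygous first) and the guidance cue gene Sema3a (-0.61 and -0.44) in the authors' deposited table. Median absolute log2 folds were 0.66 in heterozygotes and 1.88 in homozygotes, with a median difference of 0.79 per gene, all from the authors' deposited table. Genes are not independent replicates, so this is a count over genes with no p. Called genes had larger folds in homozygotes in general, and choosing genes called in both comparisons can by itself favour larger homozygous folds.

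**Figure D3:**
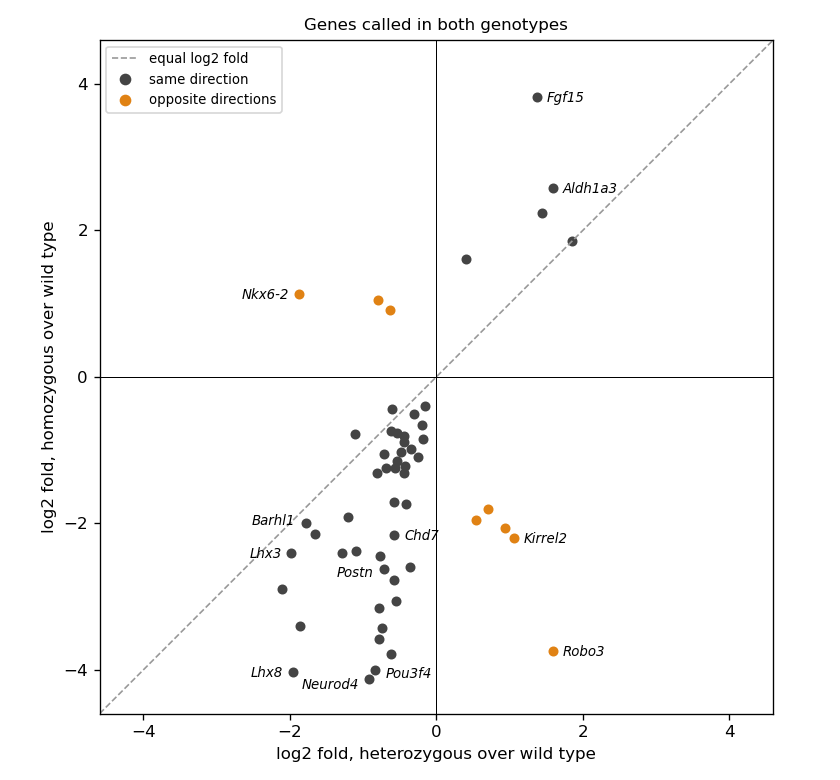
Log2 fold over wild type of the 56 genes called in both genotypes, heterozygous on the horizontal and homozygous on the vertical axis, from the authors' deposited table; each point is a gene and the dashed line marks equal folds. Grey points are the 48 genes called in the same direction and orange points the 8 called in opposite directions, and Fgf15, Neurod4 and Pou3f4 lie far to the homozygous side of the line.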

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

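Tests among the shorter or the longer called genes alone, and other measures of length, were chosen after seeing the data. Of 130 recomputed values, 107 stayed on their side of the threshold or within 1.5 times, 18 moved, 2 became and 3 ceased to be significant, and 0 reversed. A stricter adjusted p of 0.01 left 253 higher and 394 lower genes in homozygotes and 28 and 59 in heterozygotes, and 0.001 left 166 and 225, and 23 and 42. An absolute log2 fold of at least 1 left 19 higher and 32 lower genes in heterozygotes. Genes called in both in the same direction numbered 26 at an adjusted p of 0.01 and 13 at that fold, and the change was larger in homozygotes for 26 of 26 and 13 of 13. These fewer genes follow from the stricter criteria. Among the longer genes 1 list, low oxygen and glycolysis, passed; the neuroblast list, with 6 of 6 lower there, had an adjusted p of 0.685 but could not pass, as most other longer genes were lower too. The heat shock list had 0.0748 among the shorter genes (7 of 7 higher) and the ribosomal list 0.0719 at the minimum fold (4 of 4 higher), each too small to pass, while the Notch list reached 0.0215 among the shorter genes (0.0215 to 1 over its alternatives), for which the cause was not tested. Within 10 Mb of Chd7 the odds ratio of being called was 2.71, with the trapped gene itself counted among the called genes. The cause was not tested. No paired analysis was possible because the tables hold comparisons and no values per library. For the same reason leaving out replicates, other normalizations, filters on low counts and the minimum mean count were not run, depth is unknown, and leaving out infinite folds removed no gene.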

Other observations

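Tests of transcript length, of stress at collection and of neural tissue in the dissections, and the count of histone genes, were chosen after the results were seen.

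Further genes of homozygous otocysts, chosen after their values were seen, included the amino acid synthesis genes Asns (log2 1.88) and Psat1 (1.10), the stress-response genes Chac1 (3.06) and Trib3 (1.96), and the otoconin gene Oc90 (-2.21) in the authors' deposited table. Genes with histone symbols were listed 9 times as higher and 0 times as lower, with log2 folds from 1.71 to 3.06 in the authors' deposited table, although the families hold near-identical copies. Whether a difference in library preparation or RNA quality between the genotypes gave this rise was not tested. BMP and TGF-beta genes had 3 higher and 2 lower (Fisher's exact test, adjusted p 0.495), with the BMP antagonist gene Nog at 2.76 on the log2 scale of the authors' deposited table. The p53 target list had 4 higher and 2 lower (Fisher's exact test, adjusted p 0.364), including the pro-apoptotic genes Pmaip1 (log2 2.20) and Bbc3 (1.52) in the authors' deposited table. Endothelial genes also had 4 higher and 2 lower (Fisher's exact test, adjusted p 0.364), imprinted genes 4 and 1 (adjusted p 0.157), matrix genes 3 and 9 (adjusted p 0.495), erythroid genes 0 and 3 (adjusted p 0.459) and deafness genes 1 and 3 (adjusted p 1). The erythroid list, with 3 called members, was too small to pass. With too few members for a test, the muscle list had 2 higher, Acta2 (log2 3.35) and Tagln (2.94), in the authors' deposited table. The cell cycle list had 2 higher, the cyclin-dependent kinase inhibitor genes Cdkn1b (log2 1.23) and Cdkn1c (0.47) in the authors' deposited table. Neural crest had 2 lower, and the chromatin remodeller list had Chd7 alone. Smarcc2, a remodeller subunit gene outside that list, was lower in homozygotes (log2 -0.84) and in heterozygotes (-0.18) in the authors' deposited table. The surface ectoderm, macrophage, Hedgehog and Hox lists had 0 called members. Of the sex-linked list, Xist was listed as higher at a log2 fold of 9.64 in the authors' deposited table, and 0 of 4 Y-linked genes were listed; the sex of the embryos is not in the labels.

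Among the higher genes of heterozygous otocysts were the apolipoprotein gene Apob (log2 2.02), the transthyretin gene Ttr (1.98) and the alpha-fetoprotein gene Afp (1.90) in the authors' deposited table. How much tissue from outside the vesicle each dissection held was not measured. These rises therefore cannot be assigned to otic cells or to the genotype.

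Transcript length as the whole cause is argued against for the rise of the low-oxygen and glycolysis list in homozygotes. Among the longer called genes, 6 of 6 members were higher against 17.8% of the other genes there (Fisher's exact test, p 3.83e-05). Lengths were not matched further there, where the members of the list had a median of 5349 nt. Stress or low oxygen during collection of the homozygous embryos could raise the same genes; of the heat shock and immediate early genes 8 of 8 called were higher too (Fisher's exact test, adjusted p 0.00213), and 7 of 7 among the shorter called genes, where the list was too small to pass (adjusted p 0.0748). Nothing in the deposited values separates collection from genotype, so these cannot be told apart. An effect of Chd7 loss on these genes, whether direct or indirect, stays an untested alternative.

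Lower genes had longer transcripts than higher genes in homozygotes, also among genes outside every list, where the difference in median log2 length was 0.864 (permutation test, p 1e-05, the smallest these permutations can give). This is consistent with a length-dependent difference in library preparation or RNA quality between the genotypes. In heterozygotes the medians were 3459 nt for higher and 3593 nt for lower genes (permutation test, p 0.931), and the difference between the comparisons was not tested. A preference of Chd7 for regulating long genes would give the same difference, so a genotype effect stays open.

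The called ganglion, hindbrain and otic genes of homozygotes, of which the ganglion list alone passed its test, were listed as lower more often than higher. A transcript length difference as the whole cause is argued against for the neuroblast and ganglion list. Of its members among the shorter called genes, 14 of 14 were lower (Fisher's exact test, adjusted p 3.48e-05). The adjusted p was up to 0.00102 over the alternatives other than the longer genes, where the test could not pass. Lengths were not matched further among the shorter genes. For the hindbrain list (9 of 12 lower there, adjusted p 0.0778 by Fisher's exact test; 0.0778 to 1 over the alternatives) and the otic list (4 of 5, adjusted p 0.298; 0.140 to 0.298 on the same terms) a length difference stays open. Less neural tissue beside the otocyst in the homozygous dissections might account for the lower ganglion genes and would lower hindbrain genes too, of whose called members 76.9% were lower against 61.7% of all called genes (Fisher's exact test, adjusted p 0.495), with Wnt1 and Nkx6-2 higher, so this explanation cannot be told apart from an effect of genotype. Neuroblasts leaving the otocyst express many of the same genes as the ganglion, so a smaller ganglion outside the vesicle and fewer neuroblasts within it remain open.

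A gene trap made in 1 strain can carry flanking chromosome from that strain, which could add calls near Chd7 on chromosome 4. Within 20 Mb of Chd7, 8 of 87 protein-coding genes were called, an odds ratio of 2.04 (Fisher's exact test, p 0.0688). With Chd7 left out the odds ratio was 1.79 (Fisher's exact test, p 0.129), with a 95% interval of 0.82 to 3.88 that excludes neither no excess nor a large one. With Chd7 counted, the 10 Mb window gave 2.71 (Fisher's exact test, p 0.0212) and the 40 Mb window 1.45 (Fisher's exact test, p 0.146). Chd7 is the trapped gene and 1 of the 7 called genes within 10 Mb. That window was not tested without it, so its p does not show an excess of other genes.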
